A study of Mus musculus with 6 samples.

How the data were processed

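RNA was extracted from the cortex of 6 male mice with Trizol and polyadenylated RNA was selected for the libraries, per the labels' protocols. Samples were grouped by the genotype in their titles, with 3 mice per genotype. The mouse numbers do not repeat across genotypes, so no pairing was used. Trimmomatic, FastQC, HISAT2, featureCounts, DESeq2 and DESeq are named, without version, in the submitters' processing notes. The genome build, annotation, strand setting and treatment of multiply mapped reads are not given in the sources used here, and no coordinates are reported. Without a stated strand setting, reads of overlapping or antisense genes cannot be told apart.

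The deposited expression values are a signal of normalized counts, gene counts divided by a size factor for each library, per the file headers and the values themselves. Every value was a whole multiple of 1 step per column: division by the step gave whole numbers within a tolerance of 0.01 for 100% of values in each library. The size factors were 0.953, 1.034 and 1.045 for WT 909, 910 and 911 and 0.982, 1.003 and 0.998 for KO 920, 959 and 968. A second deposited table gives the authors' comparison of KO with WT: a log2 fold change with its standard error, a Wald score and a rank score by the authors, and the authors' p-value with its adjusted p-value. It has 14067 rows, 2227 of them repeats of a gene. The mean count in the authors' deposited table equals the mean of the 6 columns within 5.3e-05.

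Gene IDs were matched to symbols through the RefSeq table of assembly GRCm38.p6; 20671 of 21901 IDs (94.4%) had a symbol and 1230 did not. That assembly served for names and for which genes neighbour each other.

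Because the values are normalized and not raw counts, the main test was limma-trend on log2(normalized count + 1), without covariates, on the 16809 genes with a mean normalized count of at least 10 over the 6 libraries. P-values were adjusted by the Benjamini-Hochberg method at a threshold of 0.05, and the tests of genes and of lists were two-sided. Shares of random lists were counted in 1 direction, that of the list's own median. Fold changes are on the log2(value + 1) scale, which understates the change of low genes. Tools were R 4.3.3, limma 3.58.1, edgeR 4.0.16 and DESeq2 1.42.0, with Python for reading tables and drawing plots. edgeR's quasi-likelihood test and DESeq2 were run on the recovered reads as alternatives; they called 546 and 1194 genes, of which 528 and 519 were among the 548 of limma. Adjusted p-values that DESeq2 left undefined were kept undefined.

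The design, the tests, the gene lists, the rule for named genes and the alternatives were fixed before the data were examined. There were 44 lists, 26 of pathways or complexes and 18 of cell type or region markers. Lists with at least 5 measured members were tested with camera at a preset inter-gene correlation of 0.01, then with an estimated correlation, on ranks and with fry, which tests whether the genes of a list move on balance one way. Named genes were Taok2, Taok1 and Taok3, the 10 largest rises and 10 largest falls among called genes whose groups did not overlap and whose higher group averaged at least 50 normalized counts, up to 4 leading members of each list that passed, and up to 4 called members of any list. Genes known only by a provisional identifier were left out of the named rises and falls. Some genes that the rule takes are not reported here.

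Transcript length and GC content came from the longest GENCODE transcript of each gene and were available for 15294 tested genes (91.0%). The longest transcript need not be the one expressed, so the correction by length can be off for a gene where they differ. As an alternative chosen after seeing the data, each library's deviation was corrected by loess (span 0.3) on log length and GC content. Further alternatives were pseudocounts of 0.5 and 5, no filter, a filter of 50, TMM and equal-total scaling, and robust and weighted limma. A threshold of 0.1 and leaving out each mouse were used as well. A last alternative left out Taok2, the 16p11.2-homologous interval and near neighbours of Taok2.

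The procedure was tested on simulated data for KO against WT with counts drawn from these libraries' means over 16688 genes. It recovered 22 of 50 genes changed by 25%, 34 of 50 changed by 50%, 46 of 50 changed 2-fold and 47 of 50 changed 3-fold, with 14 false calls among 163. With depths of 43257088 to 47704535 reads, changes near the median called size of 1.24-fold were thus recovered for fewer genes than larger ones. The simulated genes were drawn independently, without the trend on transcript length that the real libraries carry. These rates may therefore not hold for the real data.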

Results

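Gene expression was measured by sequencing of polyadenylated RNA from the cortex of 6 male mice aged 21 to 23 days. The mice were 3 wild-type animals (WT 909, 910 and 911) and 3 animals carrying a Taok2 knockout (KO 920, 959 and 968). Taok2 encodes a serine/threonine kinase of the TAO family that acts upstream of MAP kinase cascades and on the cytoskeleton, and it lies in the mouse region homologous to human 16p11.2. The deposited table held normalized counts for 21901 genes. The whole reads recovered from it came to 43257088, 46305818 and 47704535 in WT 909, 910 and 911, and to 44629819, 45120561 and 45982205 in KO 920, 959 and 968. One comparison follows from this design, KO against WT, and it asks which cortical transcripts differ in mice that carry the knockout.

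Taok2 (gene ID 381921) was lower in every KO mouse than in every WT mouse. Its normalized count was 7460 ± 313 (SD, n = 3) in WT and 4736 ± 196 (SD, n = 3) in KO, so that 0.635 of the WT level remained (log2 fold change -0.66, SE 0.056, adjusted p = 3.2e-05, limma). The libraries read 7821, 7300 and 7260 in WT 909, 910 and 911, and 4631, 4614 and 4962 in KO 920, 959 and 968. Which exons the knockout removes was not given in the sources used here, and a count per gene includes reads from exons outside a deletion. The paralogue Taok1 was 7699 ± 493 in WT and 8876 ± 548 in KO (SD, n = 3 each), a log2 fold change of 0.21 that did not pass in limma (adjusted p = 0.078) but passed in DESeq2 (adjusted p = 0.026) and in the authors' deposited table (adjusted p = 0.025). With the trend on transcript length and GC content described below removed, its log2 fold change was 0.03 (adjusted p = 0.79). Taok3 was 3242 ± 68.4 in WT and 3115 ± 264 in KO (SD, n = 3 each), with adjusted p = 0.65.

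**Figure D1:**
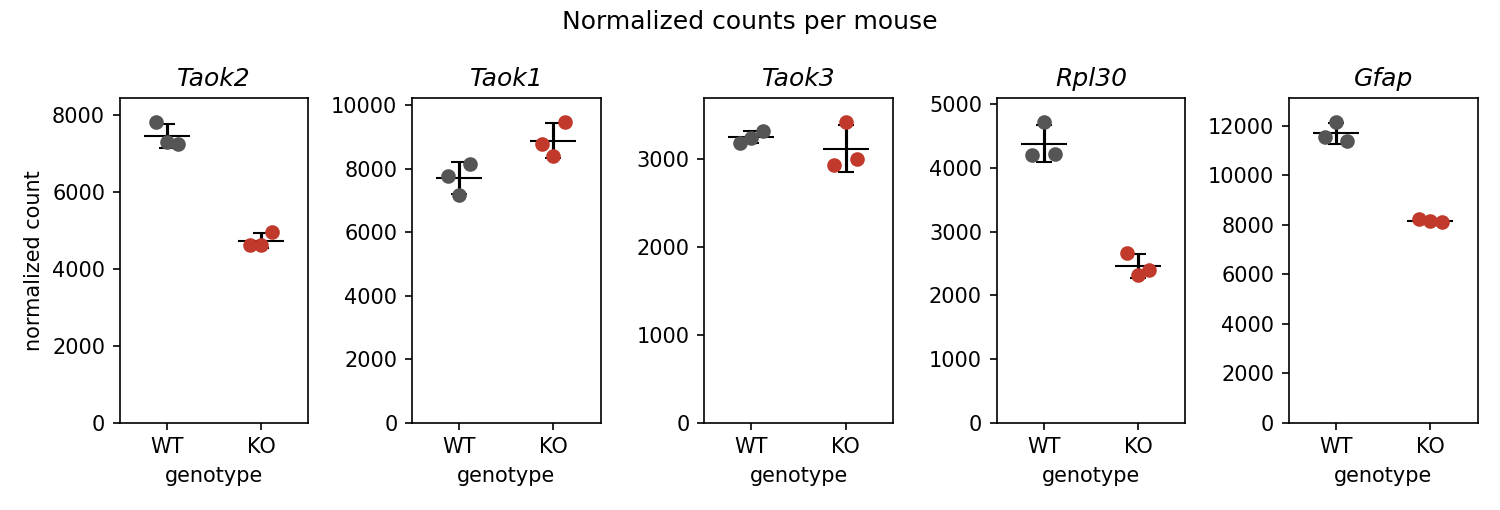
Normalized counts (vertical axes, from 0) of Taok2, Taok1, Taok3, Rpl30 and Gfap in each mouse, by genotype; points are mice, and the bar with its whiskers is the mean ± SD of 3 mice. Taok2, Rpl30 and Gfap were lower in all 3 KO mice than in all 3 WT mice.

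Of 16809 genes tested, 548 passed the adjusted p threshold of 0.05, 282 of them higher and 266 lower in KO. Most changes were small: the median absolute log2 fold change of the called genes was 0.31, a 1.24-fold difference, and 20 genes changed at least 2-fold, 10 in each direction. The ribosomal protein gene Rpl30 fell from 4383 ± 295 to 2461 ± 182 normalized counts (SD, n = 3 each; log2 fold change -0.83, SE 0.068, adjusted p = 3.2e-05). Gfap, the intermediate filament protein of astrocytes, fell from 11700 ± 407 to 8165 ± 74.7 (SD, n = 3 each; log2 fold change -0.52, SE 0.051, adjusted p = 0.00013). Coro6, which encodes an actin-binding coronin, rose from 790.9 ± 71.3 to 1259 ± 95.7 (SD, n = 3 each; log2 fold change 0.67, SE 0.087, adjusted p = 0.0027).

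Among called genes with at least 50 normalized counts in the higher group, genotypes that did not overlap and no provisional name, those with the largest rises included Bfsp2, a lens intermediate filament gene (log2 fold change 2.56, SE 0.61), and Entpd6, which encodes a nucleoside diphosphatase (0.76, SE 0.11). The axon guidance receptor Robo3 rose by 0.72 (SE 0.11) and the transcription factor Zbtb16 by 0.68 (SE 0.097). Hif3a, a hypoxia-inducible factor subunit, rose by 0.62 (SE 0.11), and the collagen gene Col24a1 by 0.74 (SE 0.16). Ubap1l, Mybpc1 and Serpinb8 rose by 0.90, 0.67 and 0.59. Bfsp2 was at 10.1 ± 2.58 normalized counts in WT and 91.5 ± 69.8 in KO (SD, n = 3 each). It read 152, 108 and 15.0 in KO 920, 959 and 968, against 12.4 in the highest WT mouse. Its fold change thus rests on KO 920 and 959 and on few reads in WT. DESeq2 set no adjusted p for Bfsp2 and Ubap1l. The call of Bfsp2 was lost without any one of WT 909, WT 910, WT 911, KO 920 and KO 959.

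Under the same conditions the largest falls were of Cbln3, a cerebellin of cerebellar granule cells (log2 fold change -1.78, SE 0.46), Dlk1, a non-canonical Notch ligand (-1.26, SE 0.28), and Trh, the thyrotropin-releasing hormone precursor (-1.25, SE 0.31). The MHC class II genes H2-Ab1 and Cd74 (the invariant chain) fell by 1.24 and 0.81 on the log2 scale. Myocilin (Myoc) fell by 0.83, from 995.6 ± 167 to 558.5 ± 91.6 normalized counts (SD, n = 3 each). Gmfg, Cdh15 and Igsf1 fell by 0.98, 0.81 and 0.77. Cbln3, H2-Ab1, Gmfg and Cdh15 had WT means between 51.8 and 99.1 normalized counts. Trh and H2-Ab1 were not called by edgeR (adjusted p = 0.064 and 0.054), and Dlk1 was not called by DESeq2 (adjusted p = 0.11). DESeq2 set no adjusted p for Cbln3, Trh, H2-Ab1, Gmfg, Cdh15 and Cd74.

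Expression differed between the genotypes along transcript length. Across 15294 genes with an annotated length, the log2 fold change rose with length (Spearman's rho 0.42 across genes, which are not independent replicates). The 1532 genes with the shortest transcripts (median 1084 nt) had a median log2 fold change of -0.16, with 129 genes that fell and 2 that rose. The 1530 with the longest (median 8394.5 nt) had a median of 0.14, with 158 genes that rose and 0 that fell. Per doubling of length, expression relative to the mean of the 6 libraries changed by -0.014, -0.077 and -0.034 in WT 909, 910 and 911 and by 0.016, 0.037 and 0.073 in KO 920, 959 and 968. Genotypes did not overlap in this slope, for which the smallest two-sided exact permutation p that 3 against 3 mice allow is 0.1. The genes outside every fixed list gave rho 0.40. With each library's trend on length and GC content removed, an alternative chosen after seeing the data, 55 genes passed in place of 548, and 51 of the 55 were among the 548. Over the 532 called genes with a length, the median ratio of the corrected to the uncorrected log2 fold change was 0.64, and the median SE moved from 0.066 to 0.055. Taok2 (-0.72), Rpl30 (-0.77), Gfap (-0.48), Coro6 (0.70), Entpd6 (0.80), Zbtb16 (0.63), Robo3 (0.65), Hif3a (0.54) and Myoc (-0.77) passed with the trend removed. Bfsp2, Ubap1l, Col24a1, Mybpc1, Serpinb8, Cbln3, Dlk1, Trh, H2-Ab1, Gmfg, Cdh15, Cd74 and Igsf1 kept their direction but not their call (adjusted p between 0.06 and 0.133). The log2 fold changes of Bfsp2 (2.64), Ubap1l (1.0), Cbln3 (-1.82), Dlk1 (-1.30), Igsf1 (-0.79) and Cdh15 (-0.82) were then slightly larger in size than before. Those of Col24a1 (0.64), Mybpc1 (0.66), Serpinb8 (0.57), Trh (-1.13), H2-Ab1 (-1.12), Gmfg (-0.91) and Cd74 (-0.70) were smaller. Their SEs hardly moved (for Bfsp2 from 0.61 to 0.63, for Cd74 from 0.185 to 0.19). For Ubap1l the unadjusted p went from 0.0011 to 0.00058, so its call ended through the adjustment, which is stricter where fewer genes have small p-values.

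**Figure D2:**
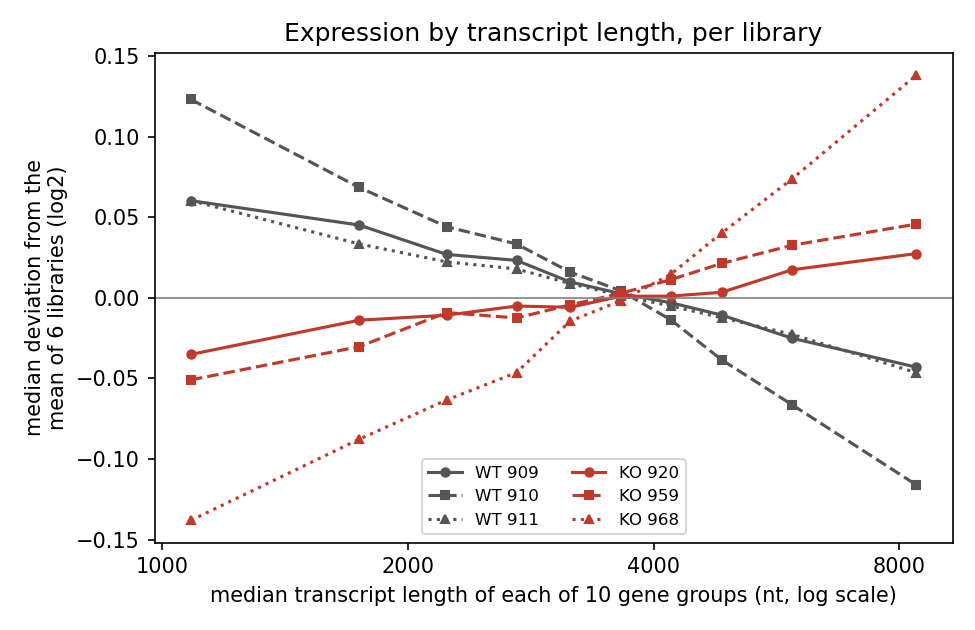
Median deviation of each library from the mean of the 6 libraries (log2, vertical axis) over 10 equal groups of genes by transcript length (nt, log scale, horizontal axis); lines are mice, grey for WT and red for KO. The group with the shortest transcripts was above the mean in the 3 WT mice (0.060 to 0.12) and below it in the 3 KO mice (-0.035 to -0.14).

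Genes of the cytosolic ribosome were lower in KO. Of 79 measured ribosomal protein genes, 53 fell, 1 rose and 25 did not pass, with a median log2 fold change of -0.28; adjusted over the list alone, 76 fell and 1 rose. Rpl11 (-0.44), Rpl13a (-0.46) and Rps14 (-0.46) fell beside Rpl30. The member that rose, Rpl29, read 193, 178 and 143 in the WT mice and 1581, 1740 and 179 in KO 920, 959 and 968. As a list the genes passed camera with a preset correlation (adjusted p = 3.2e-31) but not with an estimated one (adjusted p = 0.76 with an estimated correlation). Their median transcript length was 1059 nt, and with the length and GC trend removed their median log2 fold change was -0.14, with 11 genes lower and the list still past the threshold at the preset correlation (adjusted p = 1.4e-16). Many ribosomal protein genes have processed pseudogenes of near-identical sequence, and how the authors' counting treated shared reads was not given in the sources used here, so single values of this family are uncertain.

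Some genes of the respiratory chain and the mitochondrial ribosome were lower as well. Among 76 nuclear-encoded subunits of the respiratory chain and ATP synthase, 24 fell, 0 rose and 52 did not pass (median log2 fold change -0.19); adjusted over the list alone, 51 fell. Atp5e (-0.32), a subunit of ATP synthase, and Ndufs5 and Ndufb8 (each -0.28), subunits of complex I, were among them, as was Atp5j2 (-0.27). Of 76 mitochondrial ribosomal protein genes, 4 fell and 72 did not pass (median -0.15; 18 fell adjusted over the list alone): Mrpl14 (-0.43), Mrpl52 (-0.38), Mrpl16 (-0.31) and Mrpl23 (-0.33). No gene of the tricarboxylic acid cycle list (0 of 19, median -0.07) or of glycolysis (0 of 16, median -0.09) passed; adjusted over the list alone, 0 and 1 fell. Mdh2 was at -0.11 (adjusted p = 0.21) and Ldha at -0.19 (adjusted p = 0.063). These 4 lists passed camera with the preset correlation (adjusted p = 2.7e-20, 2.9e-12, 0.022 and 0.013) but none did with an estimated one (adjusted p = 0.76 with an estimated correlation). Their median transcript lengths were 1186, 1923, 2767 and 2609 nt, and with the trend removed their medians were -0.06, -0.05, -0.02 and -0.06. At the preset correlation the respiratory and mitochondrial ribosomal lists then still passed (adjusted p = 0.00091 and 0.0011) and the other 2 did not (adjusted p = 0.48 and 0.13), with 0 single members past the threshold in any of the 4. Of the called members named here, Mrpl23 (-0.33), Mrpl16 (-0.27), Atp5e (-0.23), Ndufb8 (-0.21) and Atp5j2 (-0.20) kept most of their log2 fold change, whereas Mrpl14 (-0.23), Mrpl52 (-0.19) and Ndufs5 (-0.08) kept less. In the same order, the lengths used were 3715, 2981, 1697, 2142 and 2101 nt, and 645, 856 and 680 nt. What a gene kept thus depends on its longest annotated transcript, which need not be the one expressed. The 13 genes encoded by mitochondrial DNA had a median of -0.02, and 0 of them passed. Their WT means ran from 112 (ATP8) to 741700 (COX1) normalized counts. The treatment of multiply mapped reads was not given in the sources used here, so values of this list are uncertain.

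Some genes of ion channels and the excitatory postsynapse were higher, while most members of these lists did not pass. Of 41 voltage-gated ion channel genes, 10 rose, 0 fell and 31 did not pass (median log2 fold change 0.20; 25 rose adjusted over the list alone). The potassium channels Kcna2 (0.28) and Kcnc1 (0.23) and the calcium channel Cacna1i (0.28) were among them. Of 40 genes of the excitatory postsynapse, 4 rose and 36 did not pass (median 0.07; 9 rose adjusted over the list alone). These were the NMDA receptor subunit Grin2a, from 1758 ± 293 to 2517 ± 386 normalized counts (SD, n = 3 each; log2 fold change 0.52), the scaffolds Homer1 (0.32) and Shank2 (0.34), and Cacng2 (0.26), an auxiliary AMPA receptor subunit. Grin2a was not called by DESeq2 (adjusted p = 0.056) or in the authors' deposited table (adjusted p = 0.055). Of 51 high-confidence autism risk genes, 5 rose, 0 fell and 46 did not pass (median 0.11; 16 rose adjusted over the list alone), including the histone methyltransferases Kmt2a (0.34) and Kmt2c (0.30) and the Ras regulator Nf1 (0.28). Of 48 axon guidance genes, the semaphorin receptor Plxna2 (0.27) rose and 47 did not pass (median 0.10; 0 adjusted over the list alone), and edgeR did not call Plxna2 (adjusted p = 0.0505). The 4 lists passed camera with the preset correlation (adjusted p = 7.0e-08, 0.0034, 4.3e-07 and 0.018) but not with an estimated one (adjusted p = 0.76 with an estimated correlation). Their median transcript lengths were 7926, 5609.5, 8237 and 5902 nt, and their medians with the trend removed were 0.05, 0.01, 0.00092 and 0.02. With the trend removed the ion channel list still passed at the preset correlation (adjusted p = 0.022), the postsynaptic, autism risk and axon guidance lists did not (adjusted p = 0.59, 0.59 and 0.97), and 0 single members passed in any of the 4. Homer1 (0.25, adjusted p = 0.0525) and Cacng2 (0.20) kept most of their log2 fold change, Grin2a (0.32) and Shank2 (0.20) somewhat less, and Kcna2 (0.11), Kcnc1 (0.10), Cacna1i (0.11), Kmt2a (0.12), Kmt2c (0.09), Nf1 (0.10) and Plxna2 (0.10) the least.

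Markers of meningeal fibroblasts, the cells of the membranes covering the brain, were lower by the largest median of any list. Of 13 markers, 4 fell, 0 rose and 9 did not pass (median log2 fold change -0.46; 8 fell adjusted over the list alone). The growth factor gene Igf2 fell from 5310 ± 83.5 to 3876 ± 445 normalized counts (SD, n = 3 each; adjusted p = 0.0061), and the organic anion transporter Slc22a6 from 352.1 ± 18.5 to 214.4 ± 52.9 (SD, n = 3 each; adjusted p = 0.027). Slc6a13 and Aldh1a2 each fell by 0.57. The median transcript length was 3894 nt, and with the trend removed the median was -0.48, the list still passed at the preset correlation (adjusted p = 9.7e-06) and Igf2 was the 1 member past the threshold. Slc22a6 (-0.75), Slc6a13 (-0.51) and Aldh1a2 (-0.51) lost their call with little change in their log2 fold change. The list passed camera with the preset correlation (adjusted p = 2.2e-05), but not with an estimated one (adjusted p = 0.76 with an estimated correlation). The mean deviations of the markers from the mean of the 6 libraries were 0.12, 0.42 and 0.08 in WT 909, 910 and 911 and -0.19, -0.04 and -0.38 in KO 920, 959 and 968.

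A few antioxidant genes and a cholesterol synthesis gene were also lower. Sod1, Gpx4 and the metallothionein Mt3 fell by 0.31, 0.31 and 0.37 among 19 genes of the oxidative stress response (16 did not pass, median -0.10; 4 fell adjusted over the list alone). Fdps, an enzyme of the mevalonate pathway, fell by 0.24 among 22 cholesterol synthesis genes (21 did not pass, median -0.12; 5 fell adjusted over the list alone). Camera with the preset correlation gave adjusted p = 0.021 and 0.0085 for these lists, and neither passed with an estimated one (adjusted p = 0.76 with an estimated correlation). Their median transcript lengths were 2294 and 3581 nt, and their medians with the trend removed were -0.03 (adjusted p = 0.32 at the preset correlation, Sod1 the 1 member past the threshold) and -0.08 (adjusted p = 0.0060, 0 members). Fdps then stood at -0.21, and Gpx4 and Mt3 each at -0.17.

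**Figure D3:**
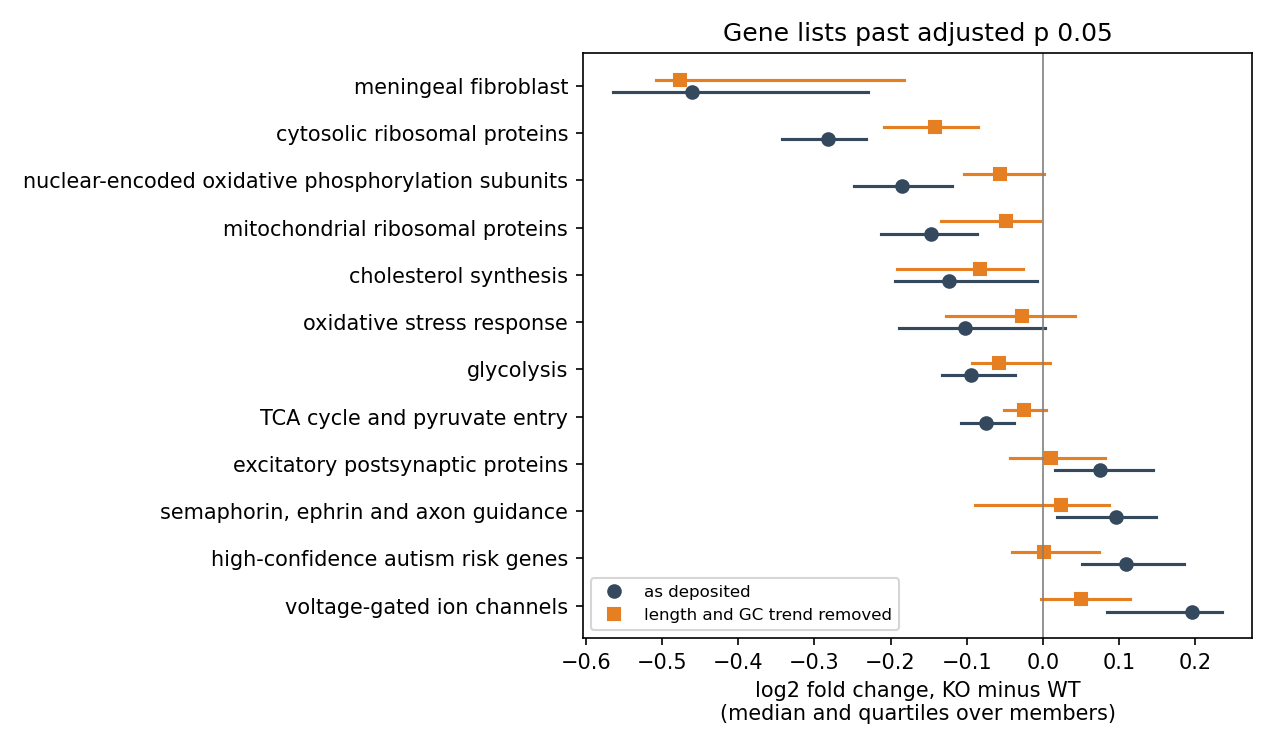
Median (symbol) and quartiles (line) of the log2 fold change, KO minus WT, over the members of the 12 gene lists that passed camera with the preset correlation, before (circles) and after (squares) removal of each library's trend on transcript length and GC content. The cytosolic ribosomal list moved from -0.28 to -0.14 and the meningeal list from -0.46 to -0.48.

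The other 32 of 44 lists did not pass, although single members did. Among activity-regulated immediate early genes, the antiproliferative gene Btg2 (-0.67) and the MAP kinase phosphatase gene Dusp1 (-0.54) fell and 18 of 20 did not pass (median -0.15). In the list of the 16p11.2-homologous interval and near neighbours of Taok2, 28 of 30 genes did not pass (median -0.05). The iron-sulphur protein gene Bola2 (-0.40) and the kinase gene Mapk3 (-0.27) fell. The upper-layer transcription factor Cux2 (0.28) rose, as did the endothelial VEGF receptors Flt1 (0.35) and Kdr (0.39), the presynaptic scaffolds Bsn (0.33) and Pclo (0.28), the clock gene Per2 (0.40) and the Wnt co-receptor gene Lrp6 (0.29). The microtubule regulators Stmn1 (-0.22) and Stmn3 (-0.23), Tubb5 (-0.22), the neuropeptide gene Cck (-0.21) and Vtn (-0.30), a pericyte marker, fell. Gfap was the single member that fell among 11 reactive astrocyte markers. Of the genes named in this paragraph, Gfap and Bola2 also passed with the length and GC trend removed. Btg2 (-0.62), Dusp1 (-0.48), Per2 (0.33), Kdr (0.31), Flt1 (0.25), Vtn (-0.21), Mapk3 (-0.20) and Tubb5 (-0.17) lost their call but kept most of their log2 fold change. Lrp6 (0.15), Cux2 (0.14), Stmn3 (-0.10), Bsn (0.08), Stmn1 (-0.06), Cck (-0.03) and Pclo (0.03) kept less. Median log2 fold changes were 0.10 for the Hippo pathway and -0.12 for microglia (adjusted p = 0.054 each), 0.09 for myelination, 0.11 for endothelial cells, 0.04 for presynaptic proteins, 0.08 for inhibitory synapses, 0.14 for interneurons, 0.04 for the JNK and p38 cascade and -0.08 for reactive astrocytes. They were -0.02 for the microtubule and septin cytoskeleton, 0.10 for upper and -0.02 for deep cortical layers, 0.02 for excitatory neurons, -0.06 for astrocytes, 0.03 for oligodendrocyte precursors, -0.05 for ependymal cells, -0.06 for choroid plexus and 0.02 for pericytes. Stress, interferon, clock and Wnt lists had medians of -0.05 (endoplasmic reticulum), 0.05 (heat shock), 0.03, 0.04 and 0.01, and mitochondrial dynamics 0.01. Marker medians were -0.04 for hippocampus, 0.02 for thalamus, -0.01 for striatum, 0.06 for erythrocytes and 0.13 for sex-linked transcripts. For the thalamus, striatum and pericyte lists the sign of the test differed from that of the median, and the mean of the sex-linked list was -0.04.

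The authors' deposited table listed 11840 genes, all with a mean normalized count of at least 217.1, of which 1201 passed adjusted p 0.05 (648 higher and 553 lower in KO). Of the 548 genes called here, 515 were among those 1201, all with the same sign, against 52.9 if the lists were independent; both lists come from the same 6 libraries. The log2 fold changes in the authors' deposited table were smaller than the log2 ratio of the group means (median ratio 0.77 over genes with an absolute log2 ratio of at least 0.3). For Taok2 the authors' deposited table gave -0.61.

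The number of called genes depended on single libraries, and was 273, 40 and 37 without WT 909, 910 and 911 and 494, 910 and 78 without KO 920, 959 and 968. The labels give no litter, batch or day, so that a batch that followed genotype and the genotype itself cannot be told apart.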

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

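The removal of the length and GC trend was chosen after seeing the data; the other alternatives were chosen before. Taok2 was called with the same direction under every alternative (log2 fold change -0.72 to -0.62), as were Rpl30, Gfap, Coro6 and Entpd6. The count of 548 genes (282 higher, 266 lower) moved to 213 (103 and 110) with no filter, where 21901 genes were tested, to 1194 (640 and 554) with DESeq2, to 1291 (661 and 630) at a threshold of 0.1, and to 55 (24 and 31) with the length and GC trend removed. Leaving out single mice gave 37 to 910 genes, 15 to 491 higher and 18 to 419 lower; the values were 273, 40 and 37 without WT 909, 910 and 911 and 78 and 910 without KO 968 and 959, each fit having fewer samples. The share of higher calls was 51.5% as deposited and 44.3% with TMM scaling. The 12 lists became 0 with the estimated correlation and 0 with fry, both from limma; other alternatives gave 10 to 16. With the trend removed the list of mitochondrially encoded genes changed sign to a median of 0.11. As a list it then passed camera at the preset correlation, with 0 single members past the threshold. Before the correction its median was -0.02 at a median length of 784 nt, against -0.16 for the tenth of genes with the shortest transcripts. Its rise thus appeared only with the correction for length. The authors' deposited table held 1862 genes at a threshold of 0.1 in place of 1201. Over single named genes, 339 values lost their call, 15 gained one and 1098 did neither; over lists, 39 lost and 28 gained a call. The cause of these moves was not tested. Depths were alike, and in simulated data 22 of 50 genes changed by 25% were recovered.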

Other observations

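The neuron-share test was chosen only after the ion channel result was seen. The second list of meningeal genes and its test were written after the main results were seen but before that list's values were. The list of cerebellar genes was written after Cbln3 and Cdh15 were seen to fall but before its own values were. Tests of both lists against length-matched lists, and with the length and GC trend removed, were chosen only after their first results were seen. With the length and GC trend removed, 11 lists passed camera at the preset correlation, 6 of them among the 12 that passed before; the estimated correlation was not applied to these values. Newly past the threshold were myelination (median log2 fold change 0.11, adjusted p = 0.0083), interneuron markers (0.15, adjusted p = 0.0064), endothelial markers (0.13, adjusted p = 0.017) and the mitochondrially encoded genes (0.11, adjusted p = 0.027), all higher, and the microtubule and septin cytoskeleton (-0.05, adjusted p = 0.0083), lower. In each of these newly passing lists 0 single members passed with the trend removed. The mitochondrially encoded genes were at a median of -0.02 before, so their rise appeared only with the correction for length. Vegfa, the ligand of the endothelial receptors Flt1 and Kdr and chosen after its values were seen, had a log2 fold change of 0.34 (adjusted p = 0.0098) and 0.35 with the trend removed (adjusted p = 0.011).

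The inactivation transcript Xist read 482, 3.87 and 4.78 in WT 909, 910 and 911 and 21.4, 3.99 and 22.1 in KO 920, 959 and 968, all labelled male. The Y-linked Ddx3y read between 3816 and 4627 in the 6 mice. Rpl29 was near 1581 and 1740 in KO 920 and 959 and between 143 and 193 in the other 4 mice.

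The real split of the mice gave 548 genes and the highest of the other splits 4; for lists the real split gave 12 and the highest other 20, and 5 of the 10 splits gave at least 12 lists. For genes the number of splits as large was 1 of 10. With 10 splits in all, a share under 0.05 is not possible.

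Medians of the ribosomal, respiratory, mitochondrial ribosomal, ion channel and autism risk lists shifted in KO along with transcript length. None of these lists passed camera with an estimated correlation (adjusted p = 0.76) or fry (adjusted p between 0.13 and 0.20). Medians lay further out than those of random lists matched on length and expression for cytosolic ribosomal (median -0.28 against -0.15 for 10000 matched lists, share as extreme 1e-04), mitochondrial ribosomal (-0.15 against -0.08, 1e-04) and ion channel genes (0.20 against 0.10, 1e-04). Here 1e-04 is the smallest share the draws can give. The respiratory list lay at the edge of its matched lists (-0.19 against -0.15). Its share of 0.0245 was also under the limit of 0.05 set before the test. The autism risk list lay where lists matched on length and expression did (0.11 against 0.11, share 0.495). The length trend itself separated the genotypes, so this match does not say what raised the list. Random genes were drawn independently, so these shares ignore that members of a list move together, and the spread between mice. They cannot decide whether the trend is the whole cause. A larger share of neurons and other causes cannot be told apart for the ion channels: 8 excitatory neuron markers had a median of 0.0203 (95% bootstrap interval -0.07 to 0.07, against 0.20), but with the trend removed 0.03 (-0.03 to 0.13), an interval that includes the ion channels' 0.05, and interneuron markers were at 0.14 before and 0.15 after. RNA quality, a library batch, pseudogene reads and the genotype itself stay open for these lists as well, and none was tested. The bootstrap used here and for the tissue lists below resampled genes, not mice, so its intervals leave out the spread between mice.

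Genes of tissue that adjoins the cortex were lower in KO: meningeal markers, and Cbln3 and Cdh15, which mark cerebellar granule cells. Less meningeal tissue in KO and other causes cannot be told apart. Of a second list of 25 meningeal genes 16 were below 0, and single members passed in both directions: 1 fell (Ptgds, -0.52) and 1 rose (Col12a1, 0.39). The median of this second list was -0.05 (95% bootstrap interval -0.18 to 0.0012, against -0.46 for the first list), as low as 0.163 of expression-matched random lists. That share lay above the limit of 0.05, set before this second list's values were seen but after those of the first list. By that limit alone the explanation would be excluded. In the tests added afterwards the share was 0.0936 for lists matched on length and expression and 0.012 with the trend removed (median -0.09, -0.20 to 0.03). The limit is therefore not relied on. More cerebellar RNA in WT and other causes cannot be told apart for Cbln3 and Cdh15: 12 other cerebellar genes had a median of -0.14 (95% bootstrap interval -0.40 to 0.02), as low as 0.0394 of expression-matched lists and 0.0143 of lists matched on length too, and with the trend removed -0.10 (-0.50 to -0.07), as low as 0.0562. Gabra6 read 0, 48.4 and 15.3 in WT 909, 910 and 911 and 4.07, 2.0 and 0 in KO 920, 959 and 968. Over the WT mice Cbln3 read 23.1, 75.4 and 64.1, in WT 909 near KO 920 (22.4). Cdh15 read 93.4, 104 and 100 in the WT mice, in the same order but nearly level. In the KO mice Cdh15 read 54.97, 56.85 and 56.14. In WT 909 Cdh15 thus stood above the KO mice although Gabra6 and Cbln3 were near KO levels. That contrast rests on 1 mouse and few reads, so it cannot decide the cause.

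Near Taok2, Bola2 and Mapk3 were lower in KO, and Atxn2l (0.32) and Srcap (0.27) were higher. Genome of another strain kept around a targeted locus would put called genes near Taok2, and 4 of 100 measured neighbours (50 on either side in GRCm38.p6) were called against 3.31% of 16232 other genes. The odds ratio was 1.22 (95% interval 0.324 to 3.24, Fisher's exact p = 0.575), an interval too wide to exclude a 3-fold excess. With the length and GC trend removed, Bola2 (-0.40, adjusted p = 0.0315, limma) and Atxn2l (0.30, adjusted p = 0.0457, limma) were among the 55 genes that passed. Mapk3 and Srcap were not. The test of neighbours was not repeated on those values. Kept genome of another strain and the loss of Taok2 thus cannot be told apart.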
